A study of Mus musculus with 3 samples.

How the data were processed

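Liver RNA of male apolipoprotein E-deficient mice was hybridised to 3 Affymetrix mouse expression arrays, 1 for each of 3 diets. Per the labels, biotinylated cRNA was prepared from 8 µg of total RNA, and the array values came from MAS5 software, per the submitters' processing notes. The software version is not given in the sources used here. Each value was the deposited MAS5 signal of a probe set, a hybridisation intensity on a linear scale. No value was negative, and the 2%-trimmed mean was 1501 on each array, so the arrays had been scaled to a common trimmed mean before deposit. Detection calls and the underlying probe intensities were not used here. Whether an array held the RNA of a single mouse or a pool is not stated in the sources used here.

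The table held 12488 probe sets, of which 66 were array controls. Gene symbols came from the platform's probe annotation, brought up to date through the Entrez identifier in a mouse RefSeq gene table of assembly GRCm38.p6, which was used for names only. A single symbol was found for 10833 probe sets, several symbols for 396, and none in the annotation used for 1193. Of the probe sets with 1 symbol, 10817 had their identifier in the RefSeq table. Probe sets with several symbols or none were left out, as were the array controls. A gene was represented by its probe set with the highest mean log2 signal over the 3 arrays, which gave 8251 genes. Other probe sets of a named gene were looked up, and disagreements are stated beside the gene.

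Signals were used without further scaling. A floor was set at the pooled median of all signals, 490.3, because low MAS5 signals cannot be told from background without detection calls. A gene was measured in a comparison when its probe set was above this floor on both arrays. Where only 1 array was above the floor, the gene is given as at least N-fold higher or lower, from the brighter signal over the floor. The fixed size for counting genes was a 2-fold difference, a log2 difference of 1. With 1 array per diet there was no replicate check on any difference, no test between diets was possible and no p-value is given. The number of arrays limits the precision of every value.

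A technical yardstick was taken from genes with several probe sets above the floor on both arrays. The difference between the log2 differences of a pair of probe sets gave the spread of a single log2 difference, which holds measurement error and probe design but not the variation between mice. Gene lists, 33 in all with 599 distinct genes of which 455 were on the array, covered lipid metabolism, liver functions, immune response, growth and stress, and markers of other cell types that a liver piece can hold. For each list the median log2 difference of its measured members was ranked among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays and is not a test of the diets. Because both comparisons with control used the same control array, their correlation and overlap are given beside values simulated for unchanged diets.

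The groups, the gene lists, the floor, the 2-fold size and the processing alternatives were chosen before the data were examined, as was the rule for named genes. That rule took the 10 genes with the largest log2 difference in each direction per comparison with control, above the floor on both arrays and at least 2 times the floor on 1. It also took the 3 highest at-least-N-fold genes in each direction, the 5 largest differences in each direction between the CLA diets, and up to 4 members of each list. Further members of the gene lists, and genes named for opposite differences on the CLA diets, were chosen after their values were seen.

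The alternatives were equal medians of the arrays, quantile normalization, floors at the pooled 25th and 75th percentile, a pseudocount of 50 signal units, the mean over all measured probe sets of a gene, and leaving out probe sets whose identifier marks possible cross-hybridisation or incomplete probe selection. The chosen probe sets of some named genes carried such a mark, among them those of Mup5, Igfbp1, Egfr, Saa2, Snrp1c-ps2 and H3c14. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The counting step was tested on simulated data for the comparison of the t10,c12-CLA and control diets, with noise of 0.3 log2 units per array over 4604 genes. It recovered 97 of 98 genes simulated at 4-fold and 88 of 100 at 2.83-fold, and placed 68 of 4381 unchanged genes past 2-fold. A simulated list of 25 genes lowered by 0.5 ranked below all random lists. All simulated changes were placed in genes above 4 times the floor on every array, so recovery of dimmer genes was not tested. The noise was a chosen value, not taken from the probe-set yardstick. The 68 unchanged genes past 2-fold therefore do not estimate how many would pass in the real comparisons.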

Results

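Gene expression was measured in the liver of apolipoprotein E-deficient male mice, a strain that develops high plasma cholesterol and atherosclerosis, after 12 weeks on 1 of 3 diets. The diets differed in a test fatty acid given at 1.0% by weight, and by the design text they were semi-purified, with fat supplying 30% of the energy. The sample labels name a western diet instead, and this difference was not resolved here. The control diet contained linoleic acid. The others contained a conjugated linoleic acid (CLA), an isomer of linoleic acid whose double bonds are conjugated, either as the c9,t11 isomer or as the t10,c12 isomer. At an age of 3 months, 29 mice were assigned to the diets, 10 to control, 10 to c9,t11-CLA and 9 to t10,c12-CLA, and 1 array per diet was analysed. The comparisons asked how each isomer at the same dose and duration differed from the control fatty acid in liver gene expression, and how the isomers differed from each other.

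The arrays were similar in overall signal. The median signal was 457 on the control array, 524 on the c9,t11-CLA array and 487 on the t10,c12-CLA array. Above the floor lay 6074, 6443 and 6214 of the 12488 probe sets, in the same order. The highest signal was 135007 on the c9,t11-CLA array, against 70778 on the control and 71111 on the t10,c12-CLA array. Across probe sets, which are not independent replicates, the log2 signals of the control array correlated with r = 0.903 with the c9,t11-CLA array and 0.924 with the t10,c12-CLA array, and the CLA arrays with r = 0.905. The ratio of the signals at the 3′ and 5′ ends of a transcript, a sign of RNA integrity, was 1.06, 0.98 and 0.78 for Gapdh and 1.40, 1.89 and 1.35 for beta-actin on the control, c9,t11-CLA and t10,c12-CLA arrays. For Pcx it was 18.3, 8.41 and 6.71, and the signals of Tfrc lay below the floor, so that its ratio was not used.

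Apoe, the gene disrupted in all of these mice, gave a signal of 6570 on the control array, 8695 on the c9,t11-CLA array and 4288 on the t10,c12-CLA array. No wild-type liver was included, and whether the probe set lies inside the disrupted part of the gene is not stated, so these signals do not check the genotype.

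On the c9,t11-CLA diet, genes of fatty acid oxidation and other targets of PPARA, the nuclear receptor for fatty acids in the liver, were lower than on the control diet. Of 25 measured genes of this list, 12 were at least 2-fold lower and none was 2-fold higher. Genes of the acute phase response, the plasma proteins that the liver secretes during inflammation, were higher, with 6 of 21 at least 2-fold higher and none 2-fold lower. Genes with higher expression in male than in female liver were higher in 8 of 8 cases, and Igfbp1 and G6pc, of the gluconeogenesis list, were 3.12-fold and 2.36-fold higher. Among 4324 measured genes, 129 were at least 2-fold higher and 120 at least 2-fold lower on the c9,t11-CLA array. The yardstick from 529 pairs of probe sets of a gene gave an SD of 0.49 for a single log2 difference, and the log2 differences of all measured genes had an SD of 0.53.

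The median log2 difference of the fatty acid oxidation list was -0.90, and 0 of 10000 matched random lists had a median as low. Cyp4a14, a fatty acid omega-hydroxylase, gave a signal of 13225 on the control and 2161 on the c9,t11-CLA array, 6.12-fold lower. Acot1, an acyl-CoA thioesterase, was 4.76-fold lower, and Vnn1, a pantetheinase, 4.15-fold lower. Enzymes of peroxisomal and mitochondrial beta-oxidation followed, with log2 differences of -1.50 for Ehhadh, -1.37 for Hadh, -1.32 for Ech1 and -1.28 for Decr1, and of -1.32 for Slc25a20, the mitochondrial acylcarnitine carrier. Ppara itself had a log2 difference of -0.28. Cpt1a, which controls the entry of fatty acids into mitochondria, stood at 0.17 and Acaa2 at 0.68. The list of fatty acid uptake and binding had a median of -0.47 over 9 genes, with 44 random lists as low. Its member Dbi, the acyl-CoA binding protein, had a log2 difference of -1.13. The bile acid list had a median of -0.37 over 13 genes, with 156 random lists as low. After quantile normalization it was -0.31, just inside the range of its random lists. Its bile acid exporter Abcc3 had a log2 difference of -1.32, and Cyp7b1, an oxysterol hydroxylase, one of 1.19.

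The acute phase list had a median log2 difference of 0.77, and 20 of its 21 measured genes were above 0, the exception being Crp at -0.51. None of the 10000 random lists had a median as high. Haptoglobin, Hp, gave a signal of 9575 on the control and 64189 on the c9,t11-CLA array, 6.70-fold higher. Serum amyloid A2, Saa2, was 3.10-fold higher by its brightest probe set and had a log2 difference of 2.58 by another. Serum amyloid P, Apcs, was 2.71-fold higher, and Orm2, Lcn2 and Itih4 were 2.65-fold, 2.61-fold and 2.11-fold higher. Several members were among the brightest signals, on the array with the highest signal ceiling. Bright secreted proteins outside this list were also higher, with albumin, Alb, 3.56-fold and Serpina1b 3.03-fold. Their list, hepatocyte secreted proteins, had a median of 0.41 over 12 genes, 9 positive and 3 negative. That median lay inside the range of its random lists and was -0.12 after quantile normalization. The 8 bacterial spike control probe sets were 1.02 to 2.12 times as bright on the c9,t11-CLA as on the control array, with the highest values for CreX, at 2.12 and 1.73. After quantile normalization the log2 difference of Saa2 was 1.09. The related pseudogene Saa-ps was at least 5.33-fold higher.

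The male-biased list had a median of 0.95 over 8 genes, above all random lists, and 3 genes were at least 2-fold higher. Egfr, the epidermal growth factor receptor, was 3.63-fold higher, and its other probe sets had log2 differences of 1.15 and 1.18. Cyp7b1, which this list shares with the bile acid list, was 2.28-fold higher, but a second probe set stood at 0.10. The major urinary protein gene Mup5 had a log2 difference of 1.01, from a probe set whose identifier marks possible cross-hybridisation. The list of gluconeogenesis and glycogen had a median of 0.70 over 6 genes, with 26 random lists as high. Pck1 and Tat, enzymes of glucose production and tyrosine breakdown, stood at 0.78 and 0.62, and Pcx, pyruvate carboxylase, at -0.70, while another probe set of Pcx stood at 0.38.

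Among genes above the floor on both arrays, the largest positive log2 differences on the c9,t11-CLA diet were those of Apoa1 at 3.74, Cyp2e1 at 3.69 and Cyp2b10 at 3.26. Apoa1, the main protein of high-density lipoprotein, gave 3111 on the control and 41606 on the c9,t11-CLA array. Cyp2e1 and Cyp2b10, cytochromes of foreign-compound metabolism, gave 3022 and 1428 on the control array against 39035 and 13715. Next came Gadd45g at 2.83, Hp at 2.74, Tff3, a secreted trefoil peptide, at 2.67, Nppa, the precursor of atrial natriuretic peptide, at 2.52, Elovl1, a fatty acid elongase, at 2.32, Snrp1c-ps2 at 2.02 and Egfr at 1.86. Ddit4, a stress-induced inhibitor of mTORC1 signalling, was at least 8.36-fold higher and Zfp787 at least 4.30-fold. The largest negative log2 differences among such genes were those of Uqcc1, an assembly factor of respiratory complex III, at -3.20, Cyp4a14 at -2.61, Krtap5-1 at -2.48, G0s2, an inhibitor of the triglyceride lipase encoded by Pnpla2, at -2.30, Acot1 at -2.25 and Vnn1 at -2.05. H2-D4 at -2.04, Btbd1 at -1.87, Oat, ornithine aminotransferase, at -1.83 and the glutathione transferase Gstm2 at -1.80 completed the 10, although a second probe set of Gstm2 stood at 0.15. Some of these differences rest on a signal just above the floor of 490.3. Such signals were 532.5 for Uqcc1 on c9,t11-CLA, and 507.5 for Gadd45g and 509.1 for Nppa on control. Dmbt1 was at least 7.67-fold lower, 2210016F16Rik at least 5.03-fold and Krt81 at least 4.99-fold. Of 32 genes whose brighter probe set differed at least 2-fold and that had a second measured probe set, the second pointed the same way in 22 and was itself 2-fold in 5.

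**Figure D1:**
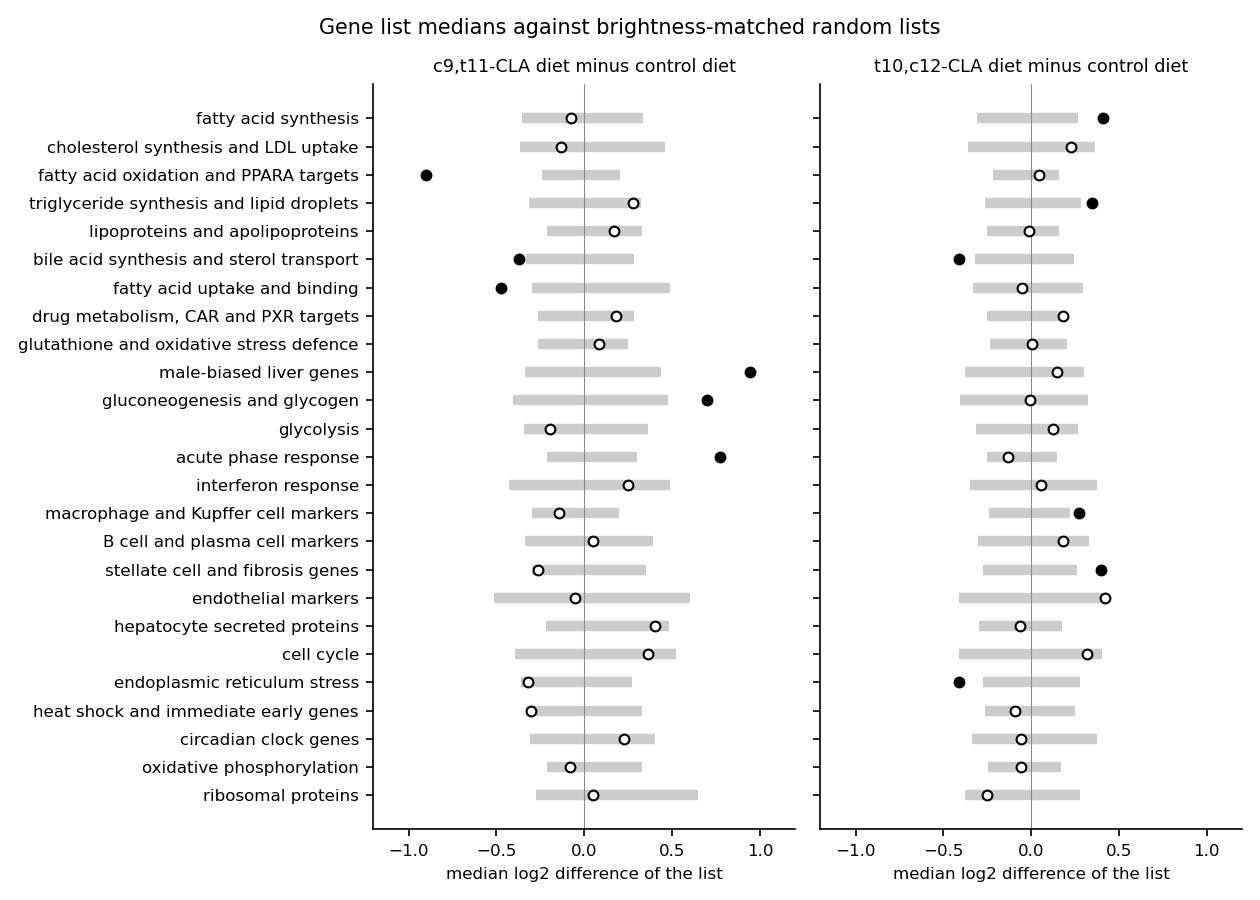
Median log2 difference from the control diet of each gene list with at least 5 measured members in both comparisons (circles), for c9,t11-CLA on the left and t10,c12-CLA on the right, with bars for the middle 95% of 10000 random lists matched on signal and filled circles for medians outside it. The fatty acid oxidation list lay at -0.90 on the c9,t11-CLA diet and at 0.04 on the t10,c12-CLA diet, and the acute phase list at 0.77 and -0.13.

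On the t10,c12-CLA diet, genes of fatty acid synthesis were higher than on the control diet in 11 of 11 measured cases, none of them by 2-fold. Genes of triglyceride and lipid droplet metabolism, of stellate cells and fibrosis, and of macrophages also had medians above their random lists, while genes of bile acid synthesis and of endoplasmic reticulum stress had medians below. The fatty acid oxidation list had a median of 0.04 over 25 genes, 13 positive and 12 negative. Of these, 2 were at least 2-fold higher, Pex11a at 1.15 and Pdk4 at 1.01, and none was 2-fold lower. Igfbp1, an insulin-repressed secreted binding protein, was 5.84-fold higher, and G6pc, the last enzyme of glucose release, 3.43-fold higher, while the gluconeogenesis list had a median of -0.01. Among 4391 measured genes, 90 were at least 2-fold higher and 82 at least 2-fold lower. The probe-set yardstick gave an SD of 0.40 for a single log2 difference over 566 pairs, and all measured genes had an SD of 0.47.

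The fatty acid synthesis list had a median log2 difference of 0.41, and 16 of 10000 random lists were as high. Fasn, fatty acid synthase, stood at 0.87, and Pgd and Me1, which supply NADPH for the synthesis, at 0.98 and 0.92. The triglyceride and lipid droplet list had a median of 0.34 over 13 genes, with 62 random lists as high. Within it Lpin1, a phosphatidate phosphatase, stood at 1.28, Pnpla2, the adipose triglyceride lipase, at 1.24, and G0s2 at -1.78. The bile acid list had a median of -0.41 over 13 genes, with 67 random lists as low. Cyp7b1 gave 11297 on the control and 3023 on the t10,c12-CLA array, 3.74-fold lower, and its second probe set had a log2 difference of -2.29. Nr0b2, a repressor of bile acid synthesis genes, stood at -1.14, Cyp7a1, the rate-limiting enzyme of that synthesis, at -0.72, and the exporter Abcc2 at 1.08.

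Stellate cell and fibrosis genes had a median of 0.40 over 13 genes, with 19 random lists as high, and 2 were at least 2-fold higher. Biglycan, Bgn, was 2.26-fold higher, its second probe set stood at 0.65, and Col4a2 was 2.22-fold higher. The fibrillar collagens Col1a1 and Col3a1 had log2 differences of 0.80 and 0.88, Col1a2 one of -0.10 and Timp1 one of 0.40. The macrophage and Kupffer cell list had a median of 0.27 over 19 genes, with 111 random lists as high. Cd14 was 2.88-fold higher, and Mpeg1, C1qc and Csf1r stood at 0.99, 0.90 and 0.78, whereas Lyz2 stood at -0.44. Medians of the lists of other cell types were 0.42 for 5 endothelial genes, 0.58 for 2 biliary-list genes, 0.32 for 4 erythroid genes, 0.18 for 8 B cell genes and -0.36 for 3 neutrophil genes, all inside the range of their random lists. The biliary-list genes were the keratins Krt8 and Krt18, at 0.94 and 0.23. Whether their signal came from bile duct cells or hepatocytes was not tested. The endoplasmic reticulum list had a median of -0.41 over 13 genes, with 27 random lists as low. The protein disulfide isomerase Pdia3 stood at -1.16, the chaperone Dnajb9 at -1.10 (a second probe set at -0.02), the transcription factor Xbp1 at -1.05, and the chaperones Hsp90b1 and Hspa5 at -0.98 and -0.86. Adipocyte markers had a median of -0.82, but only 3 were measured, and with the floor at the 25th percentile the median over 6 was 0.45.

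Among genes above the floor on both arrays, the largest positive log2 differences on the t10,c12-CLA diet were those of Gadd45g at 3.34, Apoa1 at 2.92, Myh9, non-muscle myosin, at 2.56, Ly6d at 2.55 and Igfbp1 at 2.55. They were followed by Gstm2 at 2.46, with its second probe set at -0.00, Cyp2e1 at 2.15, Isoc1 at 1.91, Pcp2 at 1.88 and Hap1 at 1.86. The control signal of Gadd45g, 507.5, lay just above the floor of 490.3. Ddit4 was at least 8.05-fold higher, Prp2 at least 4.36-fold and Foxm1 at least 3.33-fold. The largest negative log2 differences among such genes were those of the histone gene H3c14 at -2.48, Cyp7b1 at -1.90, Lifr, the leukaemia inhibitory factor receptor, at -1.79, and G0s2 at -1.78. Other probe sets of Lifr stood at -1.89 and -0.73. Hsd3b2, a steroid dehydrogenase, stood at -1.76, Keg1 at -1.73, Id2, an inhibitor of basic helix-loop-helix transcription factors, at -1.72, Mcm10 at -1.67, Phlda1 at -1.62 and the carboxylesterase Ces1c at -1.53. Hsd3b5, a male-specific steroid dehydrogenase of the liver, gave 7239 on the control and 171 on the t10,c12-CLA array, at least 14.8-fold lower, and Dmbt1 was at least 7.67-fold lower. H2-M10.1 was at least 3.14-fold lower. The male-biased list had a median of 0.15 over 7 genes, 4 positive and 3 negative, inside the range of its random lists. Drug-metabolism genes had a median of 0.18 over 17 genes, inside the range of their random lists, with Gstm3 at 1.85, Cyp2c39 at 1.53 and Gsta2 at 1.14 but Gstm1 at -1.17. Of 25 genes whose brighter probe set differed at least 2-fold, a second measured probe set pointed the same way in 19 and was itself 2-fold in 6.

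**Figure D2:**
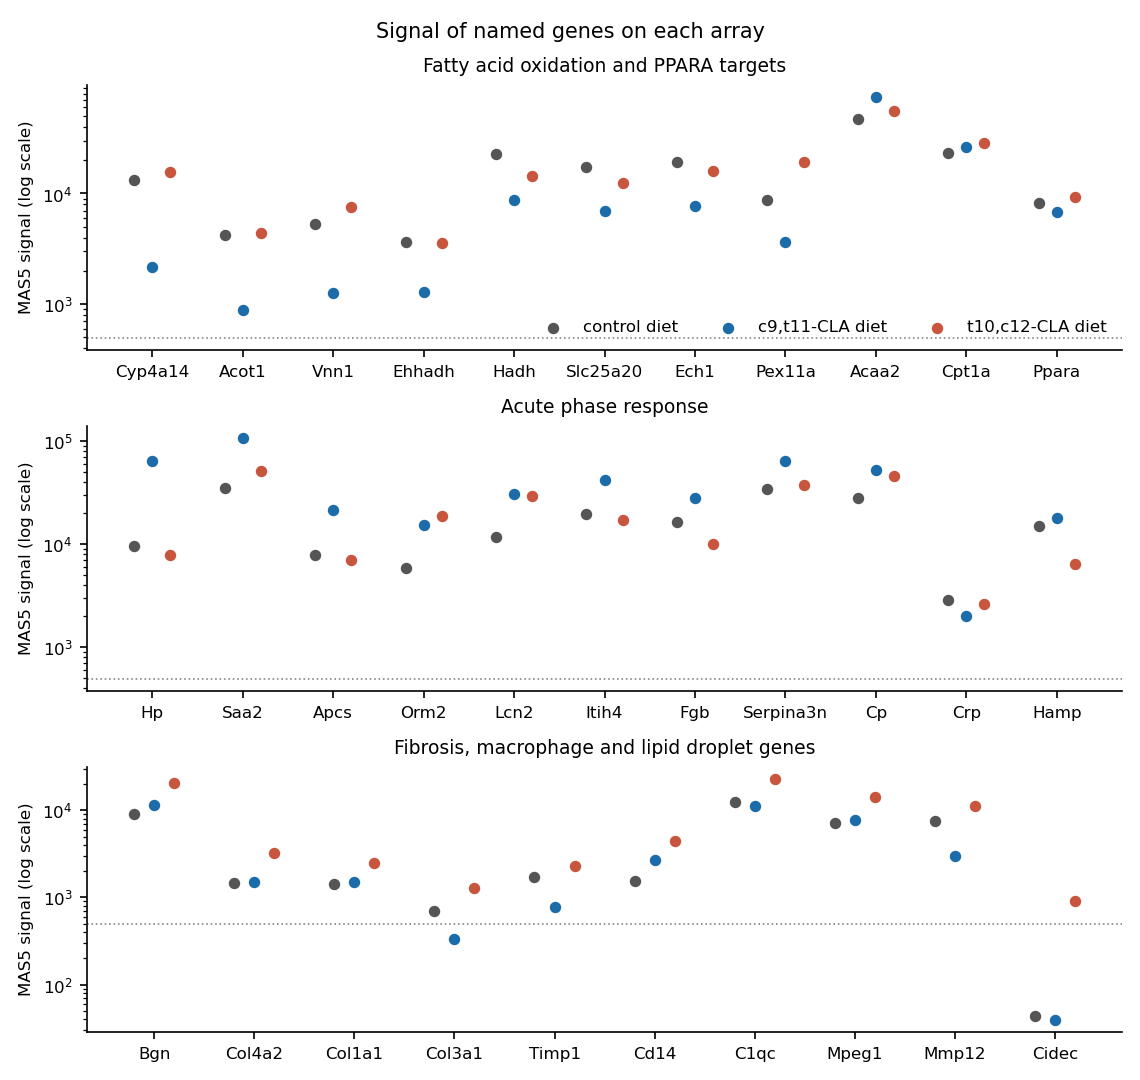
MAS5 signal on a logarithmic axis of named genes on the control (grey), c9,t11-CLA (blue) and t10,c12-CLA (red) arrays, 1 point per array, with a dotted line at the floor of 490.3. Cyp4a14 lay at 2161 on the c9,t11-CLA array against 13225 and 15776 on the control and t10,c12-CLA arrays, and Hp at 64189 against 9575 and 7859.

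The isomers, which differ in the position and geometry of the conjugated double bonds, were compared at the same dose and time. Fatty acid oxidation genes were higher on the t10,c12-CLA than on the c9,t11-CLA diet, with a median log2 difference of 0.84 and 10 of 25 genes at least 2-fold higher. Acute phase genes were lower, with a median of -0.69 and 8 of 21 genes at least 2-fold lower. Stellate cell genes were higher, with a median of 0.79 and 5 of 12 at least 2-fold higher, and macrophage genes had a median of 0.70 over 18 genes. For these 4 lists 0 of 10000 random lists lay as far out in the same direction. Among 4382 measured genes, 152 were at least 2-fold higher and 112 at least 2-fold lower on the t10,c12-CLA array, and the probe-set yardstick gave an SD of 0.49 over 553 pairs.

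Among genes above the floor on both CLA arrays, Gstm2 had the largest positive log2 difference between the isomers, at 4.26, followed by Cyp4a14 at 2.87, the microsomal glutathione transferase Mgst3 at 2.62, Vnn1 at 2.57 and the tubulin Tubb2a at 2.44. Second probe sets of Gstm2 and Tubb2a stood at -0.15 and -0.21. The largest negative log2 differences among such genes were those of Cyp7b1 at -3.09, with a second probe set at -2.39, Hp at -3.03, Snrp1c-ps2 at -2.36, Cyp2b10 at -2.17 and Egfr at -2.13. Of genes above the floor on 1 CLA array only, Ly6d was at least 19.0-fold higher on t10,c12-CLA, and Hsd3b5 and Tff3 were at least 20.5-fold and 10.6-fold lower. Of 26 genes whose brighter probe set differed at least 2-fold, a second measured probe set pointed the same way in 14 and was itself 2-fold in 6. With the pairs in 3 groups by brightness, 11 of 12 pointed the same way in the brightest group and 1 of 9 in the dimmest. Fatty acid synthesis genes had a median of 0.36 over 12 genes, 7 of them positive and 5 negative. Me1 stood at 2.01 and Pgd at 1.13, but Scd1, Srebf1 and Thrsp at -0.08, -0.09 and -0.04. Fatty acid uptake genes had a median of 0.26 over 9. Lipoprotein genes had a median of -0.46 over 18 genes, male-biased genes one of -0.78 over 7, hepatocyte secreted proteins one of -0.56 over 12 and neutrophil markers one of -0.69 over 3. Heat shock and immediate early genes had a median of 0.44 over 13, although none was at least 2-fold different. The lipoprotein, male-biased and hepatocyte medians lay inside the range of their random lists after quantile normalization, at -0.18, -0.08 and -0.02. Those of the stellate and heat shock lists lay inside it with the floor at the 75th percentile, at 0.17 and 0.12 over 4 and 6 genes, and those of the fatty acid synthesis, fatty acid uptake and neutrophil lists lay inside it under at least 1 alternative.

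Both CLA diets were then set against each other through their differences from the control array. Among 4154 genes above the floor on all arrays, 26 were at least 2-fold higher on both CLA diets, among them Gadd45g, Apoa1, Cyp2e1, Myh9, Igfbp1, G6pc, Lcn2, Orm2, Lpin1 and Pnpla2. Lower on both were 10 genes, among them G0s2, Id2 and Uqcc1. For unchanged diets sharing 1 control array, simulation gave 10.1 genes higher and 10.4 lower in both, and independent lists of these sizes would share 2.46 and 2.32. The log2 differences of the diets correlated across genes with r = 0.41 (Spearman rho 0.40), against 0.50 simulated for unchanged diets, and the covariance was 0.102 against 0.106. A single control array cannot be divided, so part of the excess of genes higher in both may come from it. The count lower in both, the correlation and the covariance did not exceed the simulated values. However, the simulation gave every array the same noise, which by itself sets the simulated correlation near 0.50. The probe-set yardstick had an SD of 0.49 for c9,t11-CLA against control, 0.40 for t10,c12-CLA against control and 0.49 between the isomers. The arrays may therefore differ in noise, so the simulated correlation and covariance cannot show whether the diets share differences. Opposite differences of at least 2-fold were seen for Cyp7b1, higher on c9,t11-CLA and lower on t10,c12-CLA, and for Arsa, Gstm2, Mgst3, Pex11a and Stx2, which were lower on c9,t11-CLA and higher on t10,c12-CLA. For these 1 and 5 genes the simulation of unchanged diets gave 0.006 and 0.004, and independent lists 2.32 and 2.46. The simulation had less spread than the data, so its counts cannot show whether opposite differences exceed noise. The variance of the log2 differences was 0.284 on c9,t11-CLA, against 0.213 simulated, and 0.221 on t10,c12-CLA, against 0.213. The simulated noise was averaged over all comparisons, so these values cannot show which diet exceeded its own noise by more. The smaller spread of the simulation also limits its counts of genes higher or lower in both. For Cyp7b1 and Gstm2 the opposite difference rested on 1 probe set each. On c9,t11-CLA their second probe sets stood at 0.10 and 0.15, and on t10,c12-CLA at -2.29 and -0.00.

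**Figure D3:**
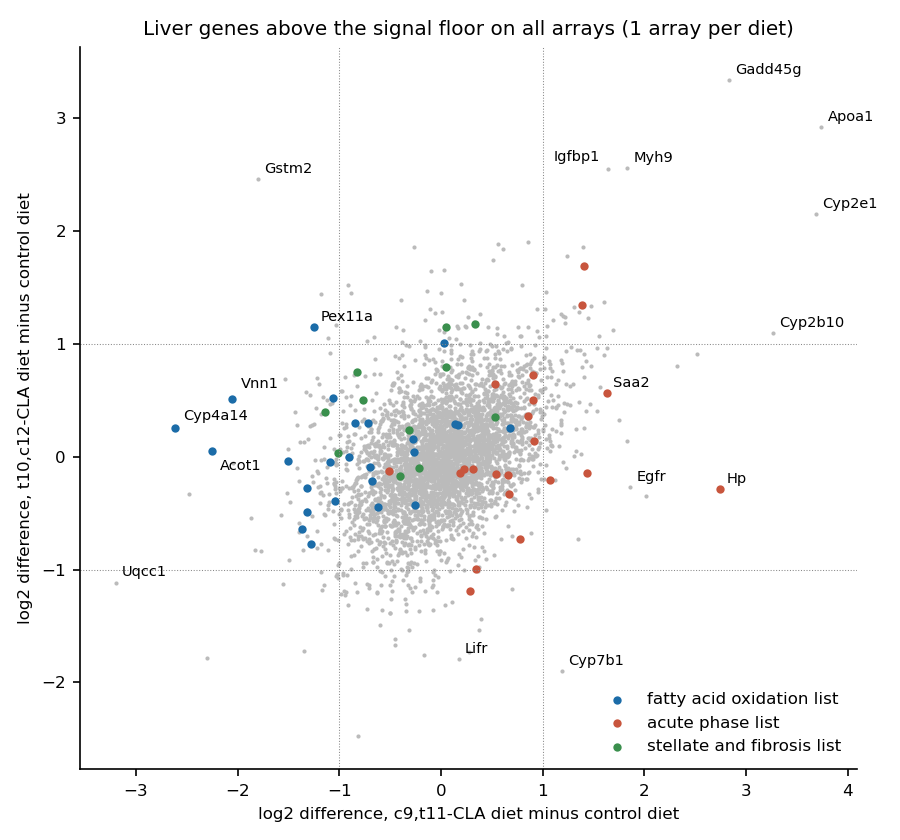
Log2 difference from the control diet on c9,t11-CLA (horizontal axis) and t10,c12-CLA (vertical axis) for the 4154 genes above the floor on all arrays (1 array per diet), with members of 3 gene lists coloured and dotted lines at 2-fold. Fatty acid oxidation genes spread to the left, as for Cyp4a14 at -2.61 and 0.25, and 23 of 25 stayed within 2-fold on the vertical axis. Pex11a, at -1.25 and 1.15, did not. Acute phase genes spread to the right, as for Hp at 2.74 and -0.28.

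Some gene lists with a measured member had a median outside the middle 95% of their random lists. They were 6 of 32 on c9,t11-CLA, 7 of 31 on t10,c12-CLA and 11 of 32 between the isomers. For lists of independently drawn genes, 1.6, 1.55 and 1.6 would lie outside. Genes of a list can vary together and some lists share members, so these are not the counts expected for unchanged diets. The medians of the lists inside the range ran from -0.32 to 0.63 on c9,t11-CLA, from -0.36 to 0.58 on t10,c12-CLA and from -0.56 to 0.52 between the isomers. Cholesterol synthesis genes were among these, with medians of -0.13 and 0.23 on the c9,t11-CLA and t10,c12-CLA diets, as were oxidative phosphorylation genes, with -0.08 and -0.06. No female-biased gene was above the floor on both arrays of either comparison with control, and no T or NK cell marker in either comparison with t10,c12-CLA.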

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

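None of the differences below was tested, since each diet had 1 array. Genes with opposite differences from control of at least 2-fold on the CLA diets are given as the log2 difference of t10,c12-CLA minus c9,t11-CLA. For Gstm2 it was 4.26, although a second probe set of this gene stood at -0.15. Mgst3 followed at 2.62, Pex11a, a peroxisomal membrane protein and PPARA target, at 2.40, Arsa, the lysosomal arylsulfatase A, at 2.20 and Stx2, a syntaxin, at 2.17. Cyp7b1 went the other way, at -3.09, but its second probe set stood at 0.10 on c9,t11-CLA, so that its opposite difference rested on 1 probe set.

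Signals of some control probe sets outside the comparisons were also higher on a CLA array than on the control array. They were chosen by a signal above the floor and at least 4 times the control signal. On the control array these probe sets lay below the floor, so that the fold values are lower bounds against the floor. A probe set for the 5′ part of mouse 18S ribosomal RNA was at least 4.11-fold and one for its middle part at least 2.02-fold brighter on the c9,t11-CLA array. The probe set for its 3′ part, above the floor on all arrays, gave 2309 on the control, 2640 on the c9,t11-CLA and 1226 on the t10,c12-CLA array. Opposite-strand probe sets of the bacterial BioB control were at least 3.49-fold, 2.98-fold and 1.75-fold brighter on the c9,t11-CLA array for the 3′, 5′ and middle parts, and on the t10,c12-CLA array at least 1.44-fold for the 3′ and 1.39-fold for the middle part. A control probe set for the middle of pyruvate carboxylase, Pcx, was at least 4.73-fold brighter on the c9,t11-CLA and at least 8.63-fold brighter on the t10,c12-CLA array. Another for its middle, above the floor on all arrays, differed less, at 4667 on the control, 5304 on the c9,t11-CLA and 7003 on the t10,c12-CLA array. In the other direction, the opposite-strand probe set for the 3′ part of the CreX control gave 548 on the control, 70.0 on the c9,t11-CLA and 101 on the t10,c12-CLA array. The ratio of the 3′ to the 5′ signal of Pcx was 18.3 on the control, 8.41 on the c9,t11-CLA and 6.71 on the t10,c12-CLA array.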

How the results depend on the processing

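All of these alternatives were planned. The correlation of the diets across genes stayed between 0.40 and 0.43 under the 7 alternatives. Of 42 counts of 2-fold genes, 30 stayed within 1.5 times the reported count, and the 12 others all came from the floor. With it at the 25th percentile, a signal of 145, where dim signals are counted, the higher and lower counts were 470 and 362 for c9,t11-CLA, 295 and 210 for t10,c12-CLA, and 425 and 394 between the isomers. At the 75th percentile, 1511, with fewer genes counted, they were 38 and 42, 40 and 38, and 60 and 42. After quantile normalization, 93 of the 129 genes higher and 107 of the 120 lower on c9,t11-CLA remained, and on t10,c12-CLA 80 of 90 and 78 of 82. Scaling moved the median of all genes by less than 0.1.

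Of 168 alternative medians of the lists outside the range of random lists, 148 moved by less than 1 SD of their random lists, 18 moved by more and 2 reversed. The reversed ones rested on few genes, adipocyte markers on t10,c12-CLA at 0.45 with the lower floor and neutrophil markers between the isomers at 0.019, from 1 gene, with the higher floor. With the higher floor the fatty acid oxidation medians were -0.78 on c9,t11-CLA and 0.63 between the isomers, the endoplasmic reticulum median on t10,c12-CLA was -0.56, and between the isomers the stellate median was 0.17 and the heat shock median 0.12. With quantile normalization the male-biased median was 0.71 on c9,t11-CLA, and between the isomers medians were -0.080 for male-biased, -0.18 for lipoprotein, -0.48 for acute phase, -0.017 for hepatocyte secreted and 0.51 for fatty acid uptake genes. The mean over probe sets gave 0.48 for fatty acid uptake and 0.56 for macrophage genes between the isomers. Leaving out marked probe sets gave there 0.48, 0.56, -1.82 for male-biased and 0.016 for heat shock genes, and -0.70 for endoplasmic reticulum genes on t10,c12-CLA. The cause was not tested. Of 2674 alternative values of named genes, 38 moved by more than the probe-set yardstick. No paired analysis was possible because each diet had 1 array.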

Other observations

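Cidec, Cd36, Fabp4, Ang, Rnase4 and Anxa5 fell outside the rule for named genes and were chosen after their values were seen. Cidec, a lipid droplet protein, gave 44 on the control, 39 on the c9,t11-CLA and 905 on the t10,c12-CLA array, at least 1.85-fold higher on t10,c12-CLA than on the others. Cd36, a fatty acid transporter, gave 75, 278 and 531, and Fabp4, a fatty acid binding protein, 373, 529 and 798, in the same order. Ang and Rnase4, neighbouring ribonuclease genes that share promoters, had log2 differences of -1.53 and -1.49 on t10,c12-CLA and of -0.32 and -0.60 on c9,t11-CLA. Anxa5, a phosphatidylserine-binding protein, stood at 1.86 on t10,c12-CLA and -0.27 on c9,t11-CLA. The metallothionein genes Mt1 and Mt2 stood at 1.08 and 1.18 on c9,t11-CLA, and Mt1 at 0.43 after quantile normalization. Of the circadian genes, Clock and Cry2 stood at 1.22 and 1.13 on c9,t11-CLA, while the list median was 0.23, inside the range of its random lists.

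The tests of explanations below were chosen after the results were seen, except that quantile normalization was chosen before the data were examined. Diet is the biological explanation that the design names. It was not tested against variation between mice or pools, since each diet had 1 array, and this stays open for every pattern below. The end ratios did not all point to the same array. Those of Gapdh and Pcx were highest on the control array, at 1.06 and 18.3, and that of beta-actin on the c9,t11-CLA array, at 1.89. Lower quality of the control RNA would bear on both comparisons with control. The quality of the control RNA was weighed only through the comparison of the isomers, which leaves out that array, and the quality of the c9,t11-CLA RNA was not weighed.

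Fatty acid oxidation genes were lower on c9,t11-CLA than on control. Scaling that depends on brightness could not account for it, since the list median was -0.97 after quantile normalization, below all random lists. A misplaced control array alone is unlikely, because without that array the median of t10,c12-CLA minus c9,t11-CLA was 0.84. A misplaced c9,t11-CLA array was not excluded, because it is part of both comparisons in which this list differed. The comparison of t10,c12-CLA with control, which leaves it out, had a median of 0.04. A more fed state would lower genes raised by fasting. The gluconeogenesis list, fixed before the data were examined, had a median of 0.70 against control, and of 0.54 after quantile normalization. Without the control array, its median for t10,c12-CLA minus c9,t11-CLA was 0.03, inside the range of its random lists. The list goes against a more fed state only relative to the control array, so it cannot decide the question. Other values went with a more fed state, with the fatty acid synthesis genes Scd1, Thrsp, Fasn and Srebf1 at 0.62, 0.59, 0.42 and 0.26, while the median of the synthesis list was -0.07.

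Acute phase genes were higher on c9,t11-CLA than on control. The c9,t11-CLA array had the highest signal ceiling, but the list median was 0.67 after quantile normalization, above all random lists. For the 11 members with a signal under 17778 on the t10,c12-CLA array, which is not part of the difference, the median was 0.77, so compression of bright signals on the control array is unlikely to account for the pattern. A misplaced control array alone is unlikely too, because without it the median of t10,c12-CLA minus c9,t11-CLA was -0.69. Here too a misplaced c9,t11-CLA array was not excluded, and without that array the median of t10,c12-CLA minus control was -0.13. The brighter spike controls on the c9,t11-CLA array, up to 2.12 times the control array, were not tested as an explanation.

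Stellate cell and macrophage genes were higher on t10,c12-CLA than on control. For the stellate genes the median between the isomers, which leaves the control array out, was 0.79. With the floor at the 75th percentile it was 0.17 over 4 genes, inside the range of its random lists. On c9,t11-CLA against control the medians were -0.26 for stellate and -0.14 for macrophage genes. The value between the isomers therefore also holds a difference of the c9,t11-CLA array. A misplaced control array was not excluded for the stellate genes. Whether a lower share of hepatocyte RNA contributes cannot be told apart from a difference in these cells. Outside the pattern, 6 lists of other cell types with at least 3 measured genes had medians from -0.82 for adipocyte to 0.42 for endothelial markers, with -0.36 for neutrophil markers. A lower hepatocyte share would raise them all only if hepatocytes do not express their genes. The adipocyte median rests on 3 genes, Car3 at -1.13, Lep at -0.82 and Lipe at 0.28. It was 0.45 over 6 genes with the floor at the 25th percentile. Car3 gave a signal of 22420 on the control array, and whether this came from adipocytes or hepatocytes was not tested. These lists therefore cannot decide the question.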
